A study of Homo sapiens with 48 samples.

How the data were processed

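RNA-seq was analysed from 48 libraries of human monocyte-derived macrophages in 12 groups of 4. The groups and the donor numbers 1, 3, 4 and 7 were taken from the sample labels, as were the 18 h treatment and the doses of 5 ng/ml LPS, 50 ng/ml R848 and 50 ng/ml polyIC. Per the labels' protocols, RNA was extracted with a Qiagen RNeasy kit, 100 ng of it went into TruSeq Stranded mRNA libraries, and 30000000 single-end reads of 50 bases per library were targeted on a NovaSeq 6000. Per the submitters' processing notes the reads were aligned with GSNAP, of which no version is named, and the builds mm10 and hg38 are both named. The gene IDs in all 48 deposited tables are human. The counting tool, its annotation and its use of strand are not given in the sources used here.

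Each table gives, per its header, a gene ID, a count, an RPKM value and a width. The counts are whole numbers of reads per gene, not normalized, and the count test below was run on them as deposited. The RPKM values were computed by the authors per kilobase of the deposited width and scaled to a library total. That total, worked back from counts, widths and RPKM, was 23500243 to 43081101 reads, of which 49.55 to 54.32% fell on the listed genes, and RPKM entered no comparison. Of the widths 77.6% are multiples of 3, so they are mostly coding lengths. Each table lists 20320 gene IDs. A symbol table named 20181 of them and GENCODE 29 named 107 more, 32 kept their ID, and 12 symbols were shared by more than 1 ID. Coordinates are from GENCODE 29 on GRCh38, matched by gene ID. To protect the donors, 45 sex-linked gene IDs were kept out of every step. Genes with near-identical copies, among them CCL3, CCL4, HLA, metallothionein and ribosomal protein genes, are uncertain where counting could split reads between copies, and so are genes that overlap on opposite strands.

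Counts on genes were 11864181 to 22319564 per library, and the 10 highest genes took 8.68 to 17.22% of them. No 2 libraries held identical counts. Levels are CPM, counts scaled to a total on genes of 1000000. Where a group held 1 to 3 counts, the ratio is given with a 95% exact counting interval, and against a group at 0 the floor is 3 counts over the group. Both cover counting error only.

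Genes were filtered with filterByExpr by group (minimum count 10, minimum total 15), which left 12618. TMM factors ranged from 0.863 to 1.1. A quasi-likelihood model in edgeR 4.0.16 with a coefficient for each of the 12 groups and a donor block was fitted to all 48 libraries (common biological coefficient of variation 0.33, 33 residual and 3.7 prior degrees of freedom). Contrasts were each stimulus against unstimulated cells in NTC, each edit against NTC in each condition, the difference in response to each stimulus between each edit and NTC, and ZC3H13 KO against WTAP KO in each condition, 21 comparisons in all. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. All design choices, the gene lists and the rule for named genes were fixed before the data were examined. Samples with the same number come from the same donor per the labels. In the check of the donor pairing, deviations from group means had a median r of 0.41 over 264 same-donor pairs of libraries, 245 of them over 0.1 and the lowest −0.21, against −0.13 between donors. Without the block, 395 genes were called for LPS in NTC, where the fit with it called 1573. The first 4 principal components held 31.7, 14.4, 11.0 and 10.2% of the variance of log counts (prior count 2). No label names a sequencing or library batch.

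The text names ZC3H13 and WTAP, and for each edit up to 8 rising and 8 falling genes called in all 4 conditions, ranked by their smallest change. It also draws on up to 3 rising and 3 falling genes per edit and condition and 5 and 5 per stimulus in NTC, ranked by fold change. These moved the same way in all 4 donors and had a mean log2 CPM of at least 2. Further, it draws on the 5 genes with the smallest adjusted p per interaction and per comparison of the edits, up to 4 members of each list described with the smallest p, and a fixed set of cytokine, receptor and m6A genes, of which IFNB1 was below the count filter. Of the genes this rule allows, only some are named. Of the 28 lists fixed, 27 had enough measured members. Each was tested in 21 comparisons with camera of limma 3.58.1, with a preset correlation of 0.01 and with an estimated one, and with fry. Benjamini-Hochberg adjustment covered the 567 list tests of each kind, and calls adjusted over the list alone were also counted.

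On simulated counts for ZC3H13 KO under LPS, the test called 49 of 100 genes changed 2-fold, 96 of 100 changed 4-fold and 7 of 12401 unchanged genes. For a difference in the LPS response in ZC3H13 KO it called 11 of 100, 71 of 100 and 6 of 12401. With no gene changed, 0 of 12601 were called for unstimulated ZC3H13 KO.

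The alternatives fixed beforehand were DESeq2 1.42.0, size factors of the relative log expression kind, no filter on low counts, no donor block, fits of only the libraries compared, limma-voom with a correlation of 0.16 within each culture (the libraries of 1 donor and edit), and leaving out each donor in turn. After the data were seen, the omission of 7 libraries that stood apart, of the 6 among them from donor 3, and of the 1 from donor 7 were added. Labels were kept as given throughout. Analyses ran in R 4.3.3 and python 3.11.15, with pandas 2.3.3 and matplotlib 3.10.9.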

Results

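RNA was sequenced from human macrophages grown from blood monocytes, in 48 libraries. The cells came from 4 donors and carried 1 of 3 edits. These were a knockout (KO) of ZC3H13, a KO of WTAP and NTC, which the labels equate with wild type. ZC3H13 and WTAP belong to the nuclear complex that writes N6-methyladenosine (m6A) on RNA. Cells were left unstimulated or were treated for 18 h with 5 ng/ml LPS, a bacterial ligand of the receptor TLR4, with 50 ng/ml R848, a synthetic ligand of TLR7 and TLR8, or with 50 ng/ml polyIC, a mimic of double-stranded RNA. This gave 12 groups of 4 libraries, 1 per donor, to ask whether each edit's effect holds across these stimuli. Counts on genes had a median of 14594964 per library. Group means ran from 13094386 ± 1047054 (SD, n = 4) in ZC3H13 KO with LPS to 17784588 ± 3039868 in unstimulated WTAP KO. Of 20320 gene IDs, 12618 were tested. Levels are CPM, mean ± SD over the 4 donors of a group. Changes are log2 fold changes ± standard error with Benjamini-Hochberg adjusted p-values from edgeR's quasi-likelihood test, and a named gene moved the same way in all 4 donors unless another number is given. Gene lists, fixed beforehand, were tested with camera. None of the 204 calls among 567 list tests held with an estimated correlation between genes, and that adjusted p stands beside each list. In 7 libraries expression stood apart from the group: donor 3 with R848 and PolyIC in each edit, donor 7 with LPS in WTAP KO. Counts of changed genes were also computed without these 7, a choice made after the data were seen.

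The targeted transcripts were examined in every library first. ZC3H13 (ENSG00000123200, GRCh38 chromosome 13, 45954465 to 46052759, minus strand) was at 51.4 to 125 CPM in the 16 ZC3H13 KO libraries and at 91 to 159 CPM in the 16 NTC libraries, and was lower than in NTC of the same donor and condition in 15 of 16 pairs. In unstimulated ZC3H13 KO cells it was 77.6 ± 16.2 CPM against 132 ± 9.45 CPM in NTC (log2 fold change −0.78 ± 0.16, adjusted p = 0.0215). Under LPS, R848 and PolyIC its log2 fold changes of −0.72 ± 0.16, −0.64 ± 0.16 and −0.67 ± 0.16 did not pass the test (adjusted p = 0.0688, 0.162 and 0.164, with 3 of 4 donors lower under PolyIC). WTAP (ENSG00000146457, GRCh38 chromosome 6, 159725585 to 159756319, plus strand) was higher, not lower, in the libraries labelled WTAP KO. It ranged from 61.5 to 295 CPM in them and from 23.7 to 167 CPM in NTC. In unstimulated cells it rose from 27.3 ± 3.62 to 161 ± 36.7 CPM (2.54 ± 0.40, adjusted p = 6.74e-06), and it rose by 1.25 ± 0.38 with R848 (adjusted p = 0.0129) and by 1.27 ± 0.39 with PolyIC (adjusted p = 0.012). With LPS its change of 0.96 ± 0.38 did not pass (adjusted p = 0.0803, 3 of 4 donors higher). The labels give no edited position, and a whole-gene count does not show a small edit, so the rise leaves the edit undecided. Libraries labelled WTAP KO are called so below. WTAP was also higher in each ZC3H13 KO library than in its paired NTC library. WTAP also rose in NTC with each stimulus, by 1.76 ± 0.39 with LPS (adjusted p = 0.00337), 1.55 ± 0.39 with R848 (adjusted p = 0.0127) and 1.6 ± 0.39 with PolyIC (adjusted p = 0.0171). GENCODE 29 places SOD2, which encodes a mitochondrial superoxide dismutase, on the opposite strand across WTAP (ENSG00000112096, chromosome 6, 159669057 to 159745186, minus strand). Strand use in counting is not given, so reads cannot be told apart where exons overlap, over 298 and 139 bases with 2 SOD2 IDs. How many lie in the WTAP width of 1256 was not tested. SOD2 was at 228 ± 138 CPM in unstimulated NTC and at 5110 ± 1350 CPM in unstimulated WTAP KO (4.39 ± 0.64, adjusted p = 2.38e-06). Of the 8 comparisons of a target with NTC, 4 passed, against 7 with DESeq2, 2 without donor 3 and 1 without donor 4.

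**Figure D1:**
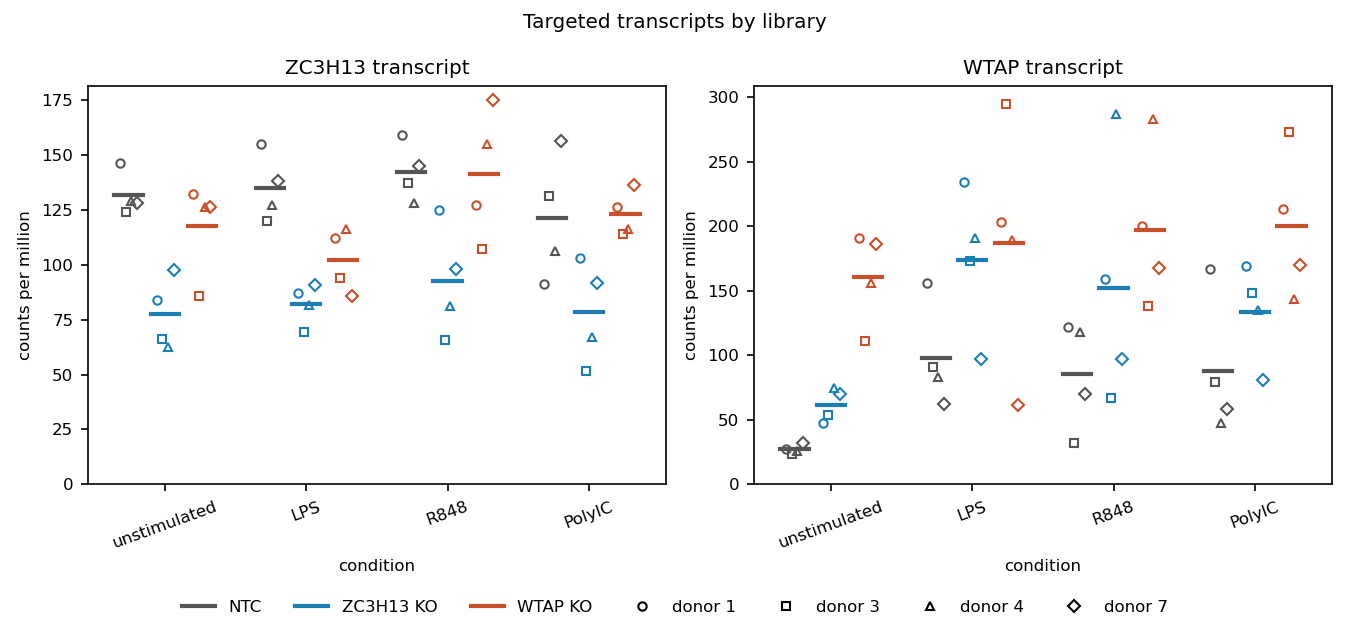
ZC3H13 (left) and WTAP (right) transcript levels in CPM, 1 point per library and 1 symbol per donor, with a bar at the mean of each group of 4 donors. ZC3H13 lies between 51.4 and 125 CPM in the ZC3H13 KO libraries, and WTAP rises from a mean of 27.3 CPM in unstimulated NTC to 161 CPM in unstimulated WTAP KO.

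In NTC cells LPS raised inflammatory genes and lowered genes of cell division. IL1B, a secreted inflammatory cytokine, went from 22.3 ± 17.3 to 4600 ± 2910 CPM (7.71 ± 2.02, adjusted p = 0.0107), and IL6 from 7.63 ± 4.17 to 185 ± 153 CPM (4.28 ± 1.20, adjusted p = 0.0168). The chemokine gene CCL5 rose by 5.22 ± 0.99 (adjusted p = 0.000973), and BIRC3 and TNFAIP3, both targets and regulators of NF-kB signalling, rose by 3.24 ± 0.46 (adjusted p = 6.18e-05) and 2.89 ± 0.47 (adjusted p = 0.000243). Of 24 NF-kB target genes 20 rose, 22 adjusted over the list alone (camera adjusted p = 8.93e-22, adjusted p = 0.249 with an estimated correlation). Of 26 inflammatory cytokines and chemokines 13 rose, 16 adjusted over the list alone (camera adjusted p = 8.22e-11, adjusted p = 0.537 with an estimated correlation). Among 17 costimulation and checkpoint genes 10 rose, 11 adjusted over the list alone (camera adjusted p = 8.92e-06, adjusted p = 0.31 with an estimated correlation). They included the T cell ligands CD80, by 2.51 ± 0.63 (adjusted p = 0.00813), and CD274, which encodes PD-L1, by 2.29 ± 0.45 (adjusted p = 0.00114). Of 43 type I interferon-stimulated genes 6 rose, 24 adjusted over the list alone (camera adjusted p = 7.57e-14, adjusted p = 0.615 with an estimated correlation). TNF, the interferon-induced CXCL10 and the antiviral IFIT1 had changes of 1.44 ± 0.71, 1.67 ± 1.68 and 1.67 ± 1.47 that did not pass (adjusted p = 0.18, 0.558 and 0.494). Of 26 cell cycle genes 25 fell, 25 adjusted over the list alone (camera adjusted p = 4.91e-23, adjusted p = 0.249 with an estimated correlation). They included the spindle factor TPX2 (−2.36 ± 0.34, adjusted p = 6.18e-05) and cyclin A2, CCNA2 (−2.44 ± 0.37, adjusted p = 0.000134). CD180, which encodes a surface protein related to TLR4, fell by 4.35 on the log2 scale (SE 0.95, adjusted p = 0.00274). Of 39 ribosomal protein genes, a list fixed as a sign of RNA quality, 5 fell, 5 adjusted over the list alone (camera adjusted p = 2.55e-08, adjusted p = 0.676 with an estimated correlation). Of 13 mitochondrially encoded genes none passed, and none adjusted over the list alone (camera adjusted p = 0.0117 for a lower list, adjusted p = 0.76 with an estimated correlation). Among 9 dendritic cell genes 2 rose and 2 fell, 2 and 3 adjusted over the list alone (camera adjusted p = 0.863, adjusted p = 0.935 with an estimated correlation). LPS raised 873 genes and lowered 700, against 1359 and 1057 without the 7 libraries and 284 and 111 without the donor block. Leaving out donor 1, 3 or 4 gave 95 and 77, 566 and 368, or 116 and 58.

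R848 also raised cytokine and NF-kB target genes in NTC. IL1B reached 6260 ± 4650 CPM (8.23 ± 2.06, adjusted p = 0.0125) and IL6 455 ± 420 CPM (6.13 ± 1.30, adjusted p = 0.00469). The NF-kB inhibitor NFKBIA rose by 2.08 ± 0.39 (adjusted p = 0.00206), BIRC3 by 2.75 ± 0.44 (adjusted p = 0.000609), SOCS3, a feedback inhibitor of cytokine signalling, by 3.21 ± 0.70 (adjusted p = 0.00542), and CD274 by 2.0 ± 0.44 (adjusted p = 0.00552). The neutrophil-attracting chemokine CXCL5, named here after its values were seen, rose by 8.15 ± 2.18 (adjusted p = 0.0186, higher in 3 of 4 donors), and TNF changed by 2.23 ± 0.72 without passing (adjusted p = 0.0554, higher in 3 of 4 donors). Of 26 inflammatory cytokines and chemokines 16 rose, 25 adjusted over the list alone (camera adjusted p = 5.95e-16, adjusted p = 0.371 with an estimated correlation). Among 24 NF-kB target genes 20 rose, 20 adjusted over the list alone (camera adjusted p = 2.88e-21, adjusted p = 0.249 with an estimated correlation). Among 26 cell cycle genes 24 fell, 25 adjusted over the list alone (camera adjusted p = 1.55e-28, adjusted p = 0.189 with an estimated correlation). CCNA2 was at −2.59 ± 0.38 (adjusted p = 0.000453) and CDCA2 at −3.09 ± 0.57 (adjusted p = 0.00187). Of 43 type I interferon-stimulated genes 1 rose, 1 adjusted over the list alone (camera adjusted p = 7.82e-07, adjusted p = 0.719 with an estimated correlation). No ribosomal protein gene and no mitochondrially encoded gene passed, none adjusted over the list alone (camera adjusted p = 0.000195 and 0.128 for lower lists, adjusted p = 0.759 and 0.863 with an estimated correlation). Among 11 neutrophil and monocyte genes 2 rose, 4 adjusted over the list alone (camera adjusted p = 0.363, adjusted p = 0.712 with an estimated correlation). Donor 3 stood apart: CXCL5 was at 1160, 1210 and 1010 CPM in the R848 libraries of donors 1, 4 and 7 and at 0.288 CPM in that of donor 3, whose PolyIC library held 229 CPM. In all, 485 genes rose and 332 fell, against 1117 and 902 without the 7 libraries, 737 and 514 without donor 3, 151 and 50 without the donor block, and 242 and 293 in a fit of only the 8 libraries compared. Without donor 1 the counts were 6 and 20, and without donor 4 no gene was called.

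PolyIC raised interferon-related genes in NTC. Of 43 type I interferon-stimulated genes 17 rose, 42 adjusted over the list alone (camera adjusted p = 2.4e-22, adjusted p = 0.475 with an estimated correlation). They included the transcription factor STAT2 (1.49 ± 0.39, adjusted p = 0.0246) and LAMP3 (4.62 ± 1.06, adjusted p = 0.0127). Of 21 interferon-gamma and guanylate-binding genes 7 rose, 17 adjusted over the list alone (camera adjusted p = 6.87e-12, adjusted p = 0.33 with an estimated correlation). Among them were the guanylate-binding protein gene GBP4 (4.23 ± 1.06, adjusted p = 0.0194) and IDO1, which encodes a tryptophan-degrading enzyme (8.25 ± 2.0, adjusted p = 0.0167). The checkpoint ligand CD274 rose by 2.58 ± 0.46 (adjusted p = 0.0033) and the costimulatory receptor CD40 by 1.96 ± 0.44 (adjusted p = 0.0122). In all 9 of 17 costimulation and checkpoint genes rose, 12 adjusted over the list alone (camera adjusted p = 2e-08, adjusted p = 0.249 with an estimated correlation). Of 24 NF-kB target genes 15 rose, 17 adjusted over the list alone (camera adjusted p = 3.95e-18, adjusted p = 0.25 with an estimated correlation). Among 26 cell cycle genes 20 fell, 26 adjusted over the list alone (camera adjusted p = 1.04e-24, adjusted p = 0.249 with an estimated correlation). The topoisomerase TOP2A was at −2.65 ± 0.52 (adjusted p = 0.00969). No ribosomal protein gene and no mitochondrially encoded gene passed, none adjusted over the list alone (camera adjusted p = 2.48e-06 and 0.0114 for lower lists, adjusted p = 0.712 and 0.759 with an estimated correlation). CXCL10, MX1 and IFIT1 had changes of 5.75 ± 2.06, 2.68 ± 1.12 and 3.38 ± 1.6 that did not pass (adjusted p = 0.091, 0.157 and 0.218) and did pass without the 7 libraries, at 6.93, 3.16 and 4.09 (adjusted p = 0.0111, 0.0125 and 0.0235). In the PolyIC libraries of donors 1, 4 and 7, CXCL10 was at 5400, 347 and 14.9 CPM, and in that of donor 3 at 2.68 CPM, whose R848 library held 69.2 CPM. In all, 400 genes rose and 232 fell, against 922 and 554 without the 7 libraries, 7 and 0 without the donor block, and none in a fit of only the 8 libraries compared (unadjusted p under 0.05 for 2621 genes, and 680 and 428 calls with DESeq2). Without donor 1 the counts were 3 and 0, without donor 4 they were 2 and 0, and without donor 7 they were 575 and 380.

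**Figure D2:**
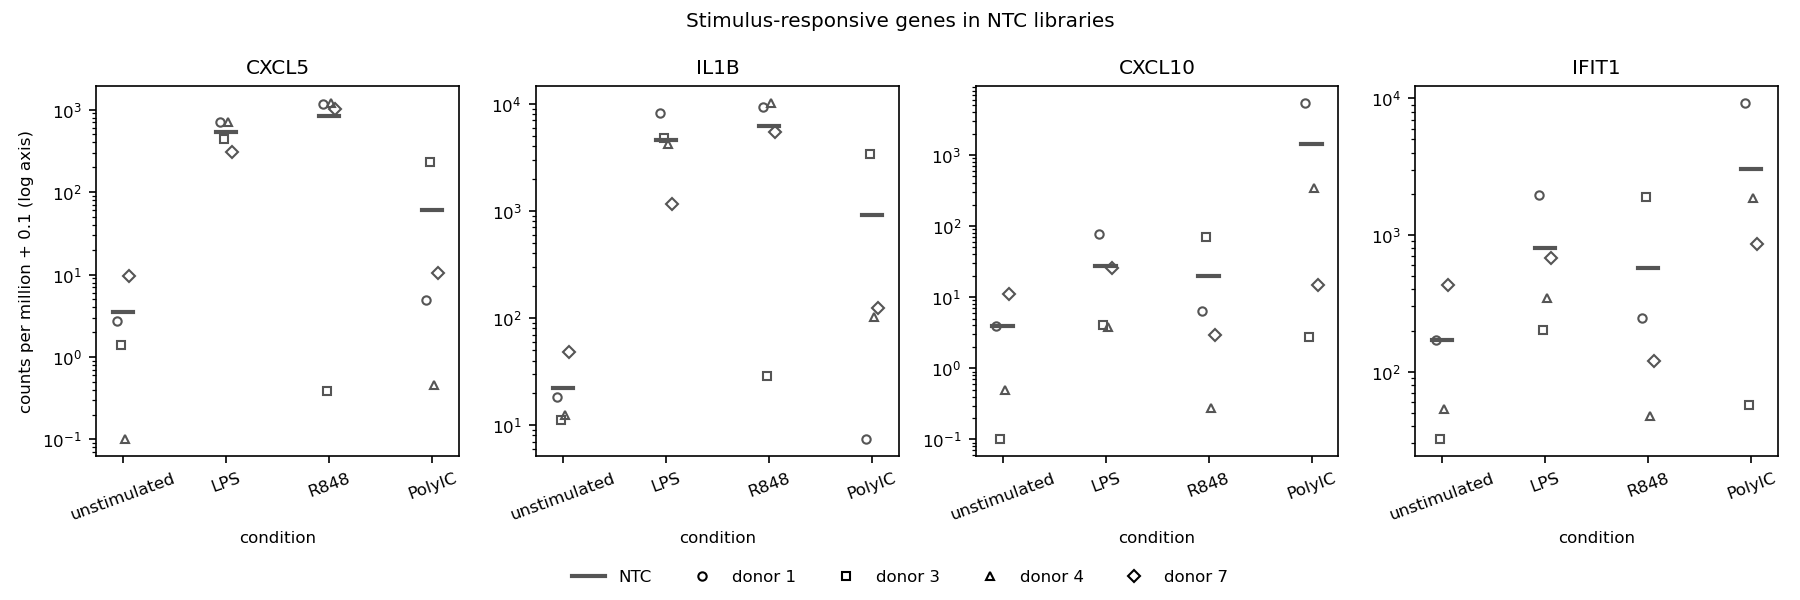
CXCL5, IL1B, CXCL10 and IFIT1 in the 16 NTC libraries, as CPM plus 0.1 on a log axis, 1 point per library and 1 symbol per donor, with a bar at the mean of each group. In donor 3 CXCL5 is at 0.288 CPM with R848 and 229 CPM with PolyIC, the reverse of the order in the other 3 donors.

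ZC3H13 KO changed few genes in unstimulated cells. In all, 19 genes rose and 2 fell, each the same way in all 4 donors, and the 2 that fell were ZC3H13 itself and TSPYL4 (−1.27 ± 0.29, adjusted p = 0.049), a gene named here after its value was seen. BIRC3 rose from 16.2 ± 11.5 to 79.2 ± 62.6 CPM (2.30 ± 0.44, adjusted p = 0.00967). PTH2R, a receptor of the parathyroid hormone family, rose by 4.70 ± 0.84 (adjusted p = 0.00557), CATSPERB, a subunit of the sperm calcium channel, by 5.00 ± 1.01 (adjusted p = 0.0215), and SGPP2, a phosphatase of sphingosine-1-phosphate, by 3.93 ± 0.89 (adjusted p = 0.049). Among 24 NF-kB target genes 1 rose, 4 adjusted over the list alone (camera adjusted p = 5.14e-15, adjusted p = 0.31 with an estimated correlation). Of 26 cell cycle genes none passed over all genes and 18 were lower adjusted over the list alone (camera adjusted p = 1e-20, adjusted p = 0.25 with an estimated correlation). TPX2 was at −1.25 ± 0.32 (adjusted p = 0.173). Of 26 inflammatory cytokines and chemokines none passed, and none adjusted over the list alone (camera adjusted p = 0.00435, adjusted p = 0.761 with an estimated correlation). IL1B was at 160 ± 215 CPM against 22.3 ± 17.3 CPM (2.86 ± 1.62), TNF changed by 0.44 ± 0.71 and IL6 by 0.66 ± 1.11, each with an adjusted p of 1, and TNF and IL6 were higher in 3 and 3 of 4 donors. No member passed, over all genes or the list alone, of the higher costimulation and checkpoint and interferon-gamma lists or the lower tissue macrophage marker and splicing factor lists (camera adjusted p = 8.85e-05, 0.0014, 0.00353 and 0.000372, adjusted p = 0.382, 0.71, 0.534 and 0.537 with an estimated correlation). No ribosomal protein gene and no neutrophil or monocyte gene passed, none adjusted over the list alone (camera adjusted p = 1.94e-05 and 0.00839 for lower lists, adjusted p = 0.731 and 0.25 with an estimated correlation). The receptor ligand CD274 changed by 1.33 ± 0.43 (adjusted p = 0.404). Without the 7 libraries 42 genes rose and 6 fell, and in a fit of only the 8 libraries compared 174 rose and 116 fell. Without donor 1, 3 or 4 the counts were 12 and 0, 0 and 0, or 1 and 0, and with DESeq2, limma-voom or no donor block they were 66 and 9, 2 and 0, or 3 and 0.

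Under stimulation ZC3H13 KO raised 10 genes with LPS, 10 with R848 and 7 with PolyIC, and lowered none by edgeR (unadjusted p under 0.05 for 500, 446 and 377 genes in either direction). These unadjusted counts are below the 1 in 20 of 12618 genes that chance alone would give. In each of the 4 conditions 5 genes rose, of 23 called in any condition. ITIH5 (ENSG00000123243, GRCh38 chromosome 10, 7559270 to 7666998, minus strand), which encodes a hyaluronan-binding protein, was at 6.46 ± 8.76 CPM in unstimulated ZC3H13 KO against 0.109 ± 0.138 CPM in NTC (5.46 ± 0.92, adjusted p = 0.00283). It rose by 5.37 ± 0.95, 4.84 ± 0.79 and 4.95 ± 0.88 under LPS, R848 and PolyIC (adjusted p = 0.0117, 0.0028 and 0.00924). MS4A6E (ENSG00000166926, chromosome 11, 60334831 to 60396596, plus strand), of the MS4A membrane protein family, rose by 4.24 ± 0.62, 4.18 ± 0.62, 3.63 ± 0.58 and 4.60 ± 0.68 in unstimulated, LPS, R848 and PolyIC cells (adjusted p = 0.000534, 0.000734, 0.0028 and 0.00073). ELOVL6 (ENSG00000170522, chromosome 4, 110045846 to 110199199, minus strand), a fatty acid elongase, went from 0.354 ± 0.34 to 5.86 ± 3.11 CPM in unstimulated cells (4.06 ± 0.62, adjusted p = 0.000853). It rose by 3.35 ± 0.65, 2.99 ± 0.57 and 3.98 ± 0.64 under the stimuli (adjusted p = 0.0149, 0.0215 and 0.00203). RBM15 (ENSG00000162775, chromosome 1, 110338506 to 110346681, plus strand), another subunit of the m6A writer complex, went from 18.4 ± 2.36 to 35.7 ± 11.4 CPM (0.91 ± 0.19, adjusted p = 0.0363). Under the stimuli it rose by 1.02 ± 0.19, 1.06 ± 0.19 and 0.95 ± 0.19 (adjusted p = 0.0145, 0.0166 and 0.0371). CYP17A1 (ENSG00000148795, chromosome 10, 102830531 to 102837533, minus strand), a steroid hydroxylase, had 332 counts over the 4 unstimulated ZC3H13 KO libraries against 3 in NTC, a ratio of 129 (95% exact counting interval 43.8 to 629, adjusted p = 0.0091). It had 336 against 3 under LPS, a ratio of 130 (44.1 to 634, adjusted p = 0.0145). With no count in NTC under R848 and PolyIC it was at least 59.3-fold and 89.9-fold higher (174 and 255 counts, adjusted p = 0.0279 and 0.028). Such bounds cover counting error only. Donor 4 was highest, at 17.9, 16.7, 5.67 and 11.9 CPM in the 4 conditions, the next donor at 2.57, 4.81, 4.5 and 2.54. BAMBI, a decoy receptor of the TGF-beta family, rose by 2.83 ± 0.58 with LPS (adjusted p = 0.0298) and 2.98 ± 0.60 with R848 (adjusted p = 0.0317), and IL1B, IL6 and TNF each had an adjusted p of 1 under every stimulus. Among lists with no member called, type I interferon-stimulated and interferon-gamma and guanylate-binding genes had higher lists under LPS (medians 0.88 and 1.12, camera adjusted p = 4.65e-09 and 1.73e-05, adjusted p = 0.697 and 0.615 with an estimated correlation). So had MHC class I pathway, costimulation and checkpoint, MHC class II pathway and pattern recognition genes (camera adjusted p = 0.000168, 0.000186, 0.0241 and 0.0409, adjusted p = 0.671, 0.411, 0.759 and 0.697 with an estimated correlation). Cell cycle and splicing factor genes had lower lists under LPS, cholesterol synthesis genes higher ones under R848 and PolyIC and stress response genes under PolyIC (camera adjusted p = 2.1e-05, 0.0282, 0.00383, 0.00237 and 0.0322, adjusted p = 0.671, 0.712, 0.712, 0.712 and 0.466 with an estimated correlation). None of these members passed adjusted over the list alone either. Of 8 m6A writer genes 1, RBM15, rose under R848, 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0409, adjusted p = 0.503 with an estimated correlation). Of the lists fixed for RNA quality and other cells, ribosomal protein genes had lower lists under LPS and PolyIC and mitochondrially encoded genes higher ones under R848 and PolyIC (camera adjusted p = 2.5e-05, 0.00748, 7.99e-06 and 0.00118, adjusted p = 0.738, 0.837, 0.62 and 0.712 with an estimated correlation). Neutrophil and monocyte genes had lower lists under LPS, R848 and PolyIC and platelet and erythroid genes under LPS and R848 (camera adjusted p = 0.0318, 0.00549, 0.0272, 0.0311 and 0.0257, adjusted p = 0.371, 0.25, 0.344, 0.537 and 0.537 with an estimated correlation). No member of these lists passed, and adjusted over the list alone 1 neutrophil and monocyte gene was lower under LPS. Each stimulated count fell to 3 or fewer when donor 1, 3 or 4 was left out and, apart from R848 without donor 7 at 13, to 5 or fewer without donor 7. Without the 7 libraries the counts were 15 higher and 2 lower for LPS, 14 and 0 for R848 and 12 and 0 for PolyIC, limma-voom and the fit without the donor block called none, and DESeq2 gave 18 and 2, 17 and 1, and 15 and 1. Fits of only the 8 libraries compared gave 108 and 71 for LPS, 2 and 0 for R848 and none for PolyIC, with 0 genes common to the 4 conditions.

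**Figure D3:**
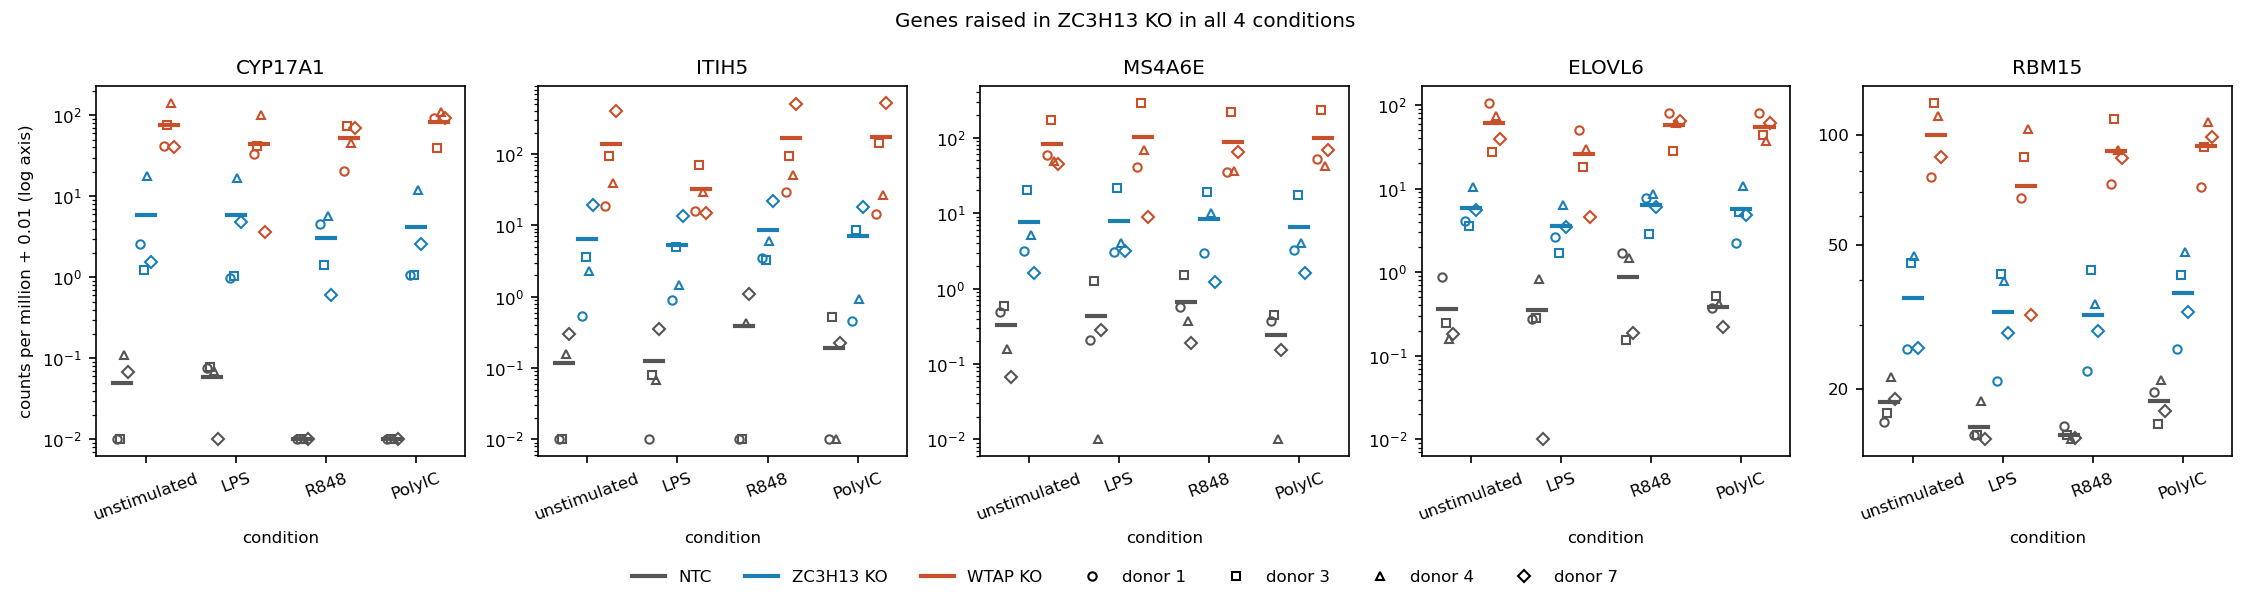
The 5 genes that rose in ZC3H13 KO in all 4 conditions, as CPM plus 0.01 on a log axis, in NTC, ZC3H13 KO and WTAP KO, with 1 point per library and a bar at the mean of each group. ELOVL6 goes from 0.354 CPM in unstimulated NTC to 5.86 CPM in ZC3H13 KO, and the mean of each gene is higher in WTAP KO than in ZC3H13 KO in each condition.

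The test of whether a stimulus acted differently in ZC3H13 KO than in NTC called no gene for LPS, R848 or PolyIC by edgeR (unadjusted p under 0.05 for 126, 123 and 108 genes). DESeq2 called 3, 3 and 2 genes, all with a weaker response in ZC3H13 KO. The difference in the response of IL1B was −3.62 for LPS, −2.91 for R848 and −3.17 for PolyIC, each with an adjusted p of 1 and the last lower in 3 of 4 donors. On simulated counts for the LPS comparison, the same test recovered 11 of 100 genes with a 2-fold difference in response and 71 of 100 with a 4-fold one. A 2-fold difference was thus mostly not detectable with 4 donors. The simulated genes had the spread typical of their level, and those changed had a mean log2 CPM above 2. The recovery therefore does not hold for genes with a larger spread or a lower level, where larger differences may also be missed.

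WTAP KO changed 5237 of 12618 genes in unstimulated cells, 2859 higher and 2378 lower. Inflammatory genes rose without any stimulus. Of 26 inflammatory cytokines and chemokines 23 rose and 1 fell, 24 and 1 adjusted over the list alone (camera adjusted p = 9.93e-05, adjusted p = 0.712 with an estimated correlation). Among 24 NF-kB target genes 22 rose, 22 adjusted over the list alone (camera adjusted p = 5.66e-10, adjusted p = 0.495 with an estimated correlation). IL1B went from 22.3 ± 17.3 to 4920 ± 7690 CPM (7.77 ± 2.02, adjusted p = 0.0024), IL6 from 7.63 ± 4.17 to 94.8 ± 44.1 CPM (4.97 ± 1.26, adjusted p = 0.00185) and TNF from 4.69 ± 1.77 to 54.0 ± 30.7 CPM (3.55 ± 0.75, adjusted p = 0.0003). CD274 rose by 3.66 ± 0.47 to 270 ± 128 CPM (adjusted p = 3.09e-07), CD40 by 2.36 ± 0.44 (adjusted p = 6e-05) and the maturation marker CD83 by 2.34 ± 0.29 (adjusted p = 1.84e-07). In all 10 of 17 costimulation and checkpoint genes rose and 1 fell, 10 and 2 adjusted over the list alone (camera adjusted p = 0.00438, adjusted p = 0.593 with an estimated correlation). Of 21 interferon-gamma and guanylate-binding genes 13 rose, 14 adjusted over the list alone (camera adjusted p = 2.07e-05, adjusted p = 0.615 with an estimated correlation). Among 43 type I interferon-stimulated genes 3 rose and 6 fell, 1 and 0 adjusted over the list alone (camera adjusted p = 0.808, adjusted p = 0.966 with an estimated correlation). IFIT1 was at −4.15 ± 1.67 (adjusted p = 0.0441) and LAMP3 at 4.04 ± 1.04 (adjusted p = 0.00218). Among 25 anti-inflammatory and tissue macrophage markers 4 rose and 11 fell, 4 and 12 adjusted over the list alone (camera adjusted p = 0.0541, adjusted p = 0.676 with an estimated correlation). The scavenger receptor CD163 went from 3130 ± 1890 to 677 ± 486 CPM (−2.35 ± 0.43, adjusted p = 5.09e-05), and the phagocytic receptor MERTK was at −4.15 ± 0.57 (adjusted p = 8.27e-07). All 26 cell cycle genes fell, 26 adjusted over the list alone (camera adjusted p = 3.25e-18, adjusted p = 0.25 with an estimated correlation). The cytokinesis factor ANLN went from 57.1 ± 19.8 to 1.6 ± 1.6 CPM (−5.63 ± 0.65, adjusted p = 4.44e-08). Of 8 m6A writer genes 5 rose, 5 adjusted over the list alone (camera adjusted p = 0.00751, adjusted p = 0.31 with an estimated correlation). RBM15 was at 2.42 ± 0.20 (adjusted p = 1.53e-10), and the m6A reader YTHDF2 rose from 104 ± 5.76 to 300 ± 46.6 CPM (1.52 ± 0.17, adjusted p = 2.84e-08). MMP3, a matrix metalloproteinase, had 140394 counts over the 4 libraries against 3 in NTC, a ratio of 49800 (95% exact counting interval 17000 to 241000, adjusted p = 2.78e-05). Markers of other cells also moved. Of 9 fibroblast and endothelial genes 5 rose and 1 fell, 6 and 1 adjusted over the list alone (camera adjusted p = 0.228, adjusted p = 0.676 with an estimated correlation). The collagen gene COL1A1 was at 2.43 ± 0.60 (adjusted p = 0.00158). Among 11 neutrophil and monocyte genes 4 fell, 4 adjusted over the list alone (camera adjusted p = 0.131, adjusted p = 0.593 with an estimated correlation). Among 9 dendritic cell, 5 platelet and erythroid and 5 T and NK cell genes, 2, 0 and 3 rose and 5, 2 and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.543, 0.218 and 0.521, adjusted p = 0.863, 0.712 and 0.83 with an estimated correlation). Of 39 ribosomal protein genes 34 fell, 34 adjusted over the list alone (camera adjusted p = 4.91e-11, adjusted p = 0.615 with an estimated correlation). Among 13 mitochondrially encoded genes 1 rose, none adjusted over the list alone (camera adjusted p = 0.252, adjusted p = 0.885 with an estimated correlation). Without donor 4 the counts were 1917 and 1649, the lowest of the 4, and without the donor block 2053 and 1411.

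Under LPS, WTAP KO raised 1333 genes and lowered 826. Of 26 cytokines and chemokines 2 rose, 2 adjusted over the list alone (camera adjusted p = 0.769, adjusted p = 0.944 with an estimated correlation). IL1B, IL6 and TNF had differences of −0.40 ± 1.5, 0.03 ± 1.04 and 0.94 ± 0.69 (adjusted p = 0.889, 0.987 and 0.373, higher in 1, 2 and 3 of 4 donors). Of 21 interferon-gamma and guanylate-binding genes 11 rose, 14 adjusted over the list alone (camera adjusted p = 0.000139, adjusted p = 0.671 with an estimated correlation). The chemokine CXCL9 was at 7.53 ± 1.80 (adjusted p = 0.00376) and CXCL10 at 5.57 ± 2.0 (adjusted p = 0.0491, 3 of 4 donors). Of 43 type I interferon-stimulated genes 1 rose, none adjusted over the list alone (camera adjusted p = 0.0171 for a higher list, adjusted p = 0.872 with an estimated correlation). Without the donor 7 library, 7 rose, 1 adjusted over the list alone. CD274 was at 379 ± 116 CPM against 108 ± 65 CPM (1.98 ± 0.44, adjusted p = 0.0019), and the anti-inflammatory cytokine IL10 rose by 2.30 ± 0.66 (adjusted p = 0.014). CD163 fell by 1.53 on the log2 scale (SE 0.42, adjusted p = 0.00998). Among 26 cell cycle genes 15 fell, 18 adjusted over the list alone (camera adjusted p = 2.51e-09, adjusted p = 0.523 with an estimated correlation). ANLN was at −2.76 ± 0.60 (adjusted p = 0.00169). Of 5 platelet and erythroid genes 4 fell, 5 adjusted over the list alone (camera adjusted p = 0.00187, adjusted p = 0.31 with an estimated correlation). Among 9 fibroblast and endothelial and 5 T and NK cell genes 3 and 2 rose and 1 and 1 fell, and adjusted over the list alone 4 and 2 rose and 1 and 1 fell (camera adjusted p = 0.17 and 0.978, adjusted p = 0.615 and 0.989 with an estimated correlation). Among 11 neutrophil and monocyte genes 4 fell, 4 adjusted over the list alone (camera adjusted p = 0.00839, adjusted p = 0.25 with an estimated correlation). Among 39 ribosomal protein genes 5 fell, 3 adjusted over the list alone (camera adjusted p = 2.02e-08, adjusted p = 0.676 with an estimated correlation). Without the donor 7 library 2 and 27 fell, 2 and 34 adjusted over the list alone. Of 9 dendritic cell genes 3 rose, 6 adjusted over the list alone (camera adjusted p = 0.668, adjusted p = 0.885 with an estimated correlation). They included the antigen-presenting CD1C (3.56 ± 0.89, adjusted p = 0.00529, higher in 3 of 4 donors), which changed by −0.19 without the 7 libraries. In the donor 7 library, over 2515 genes that changed alike in the other 3 conditions, the median WTAP KO change was 13.4% of the change of that donor there, against 81.2, 91.8 and 88.9% in donors 1, 3 and 4. Leaving out the donor 7 library gave 1957 and 1511, and leaving out all 7 gave 2061 and 1886. Without donor 3 or 4 the counts were 595 and 382 or 316 and 132, without the donor block 582 and 243, and in a fit of only the 8 libraries compared 139 and 104.

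Under R848, WTAP KO raised 2033 genes and lowered 1694. The collagenase MMP1 rose by 6.92 ± 1.70 (adjusted p = 0.00218) and the protease inhibitor SERPINB2 by 7.18 ± 2.08 (adjusted p = 0.00839). Of 26 cytokines and chemokines 2 rose and 2 fell, 1 and 1 adjusted over the list alone (camera adjusted p = 0.425, adjusted p = 0.907 with an estimated correlation). TNF rose by 1.85 ± 0.70 (adjusted p = 0.0435) and TNFSF15, a ligand of the TNF family, by 2.93 ± 0.81 (adjusted p = 0.00593), and the monocyte-attracting chemokine CCL2 fell (−1.97 ± 0.73, adjusted p = 0.0387). IL1B and IL6 had differences of 1.29 ± 1.52 and −0.08 ± 1.04 (adjusted p = 0.557 and 0.964, each higher in 3 of 4 donors). CD274 rose by 1.80 ± 0.44 (adjusted p = 0.00193) and TLR8, a receptor of R848, by 1.01 ± 0.39 (adjusted p = 0.0454). The scavenger receptor STAB1 fell (−4.85 ± 0.96, adjusted p = 0.000257), as did the chemokine receptor CCR2 (−5.03 ± 1.12, adjusted p = 0.00092) and TLR4 (−0.99 ± 0.22, adjusted p = 0.00111). Among 26 cell cycle genes 14 fell, 15 adjusted over the list alone (camera adjusted p = 2.13e-05, adjusted p = 0.671 with an estimated correlation). Among 43 type I interferon-stimulated genes 4 fell, 1 adjusted over the list alone (camera adjusted p = 0.0131, adjusted p = 0.864 with an estimated correlation). SAMD9 was at −2.69 ± 0.66 (adjusted p = 0.00204). All 5 platelet and erythroid genes fell, 5 adjusted over the list alone (camera adjusted p = 0.00835, adjusted p = 0.408 with an estimated correlation). Among 9 fibroblast and endothelial and 5 T and NK cell genes 4 and 2 rose and 2 and 1 fell, and adjusted over the list alone 5 and 3 rose and 2 and 1 fell (camera adjusted p = 0.408 and 0.733, adjusted p = 0.75 and 0.887 with an estimated correlation). Among 11 neutrophil and monocyte genes 4 fell, 4 adjusted over the list alone (camera adjusted p = 0.0449, adjusted p = 0.408 with an estimated correlation). Of 39 ribosomal protein genes 23 fell, 28 adjusted over the list alone (camera adjusted p = 1.5e-08, adjusted p = 0.676 with an estimated correlation), and of 13 mitochondrially encoded genes 2 rose, 2 adjusted over the list alone (camera adjusted p = 0.0161, adjusted p = 0.761 with an estimated correlation). Without donor 4 the counts were 1193 and 1029, the lowest of the 4, without the donor block 1255 and 795, and in a fit of only the 8 libraries compared 1238 and 928.

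Under PolyIC, WTAP KO raised 1966 genes and lowered 1715. SERPINB2 rose by 9.62 ± 2.29 (adjusted p = 0.00173), TNFSF15 by 4.10 ± 0.86 (adjusted p = 0.000448), IL10 by 2.37 ± 0.67 (adjusted p = 0.00682), TLR8 by 1.52 ± 0.39 (adjusted p = 0.00343) and CD274 by 1.30 ± 0.43 (adjusted p = 0.0219). CD274 no longer passed without the 7 libraries (1.14, adjusted p = 0.104). IL1B, TNF and IL6 had differences of 2.23 ± 1.59, 1.43 ± 0.69 and 1.45 ± 1.05 that did not pass (adjusted p = 0.299, 0.116 and 0.309) and did pass without the 7 libraries, at 4.79, 1.97 and 2.29 (adjusted p = 0.00601, 0.0141 and 0.0402). Of 26 cytokines and chemokines 5 rose, 4 adjusted over the list alone (camera adjusted p = 0.0141, adjusted p = 0.798 with an estimated correlation). STAB1 fell (−4.61 ± 0.96, adjusted p = 0.00046), as did CD163 (−1.53 ± 0.42, adjusted p = 0.00544) and the G protein regulator RGS18 (−4.42 ± 0.95, adjusted p = 0.000618). Of 26 cell cycle genes 14 fell, 15 adjusted over the list alone (camera adjusted p = 2.83e-05, adjusted p = 0.673 with an estimated correlation). Among 43 type I interferon-stimulated genes 3 fell, 1 adjusted over the list alone (camera adjusted p = 0.0313, adjusted p = 0.884 with an estimated correlation). SAMD9 was at −2.93 ± 0.66 (adjusted p = 0.00106). Of 9 fibroblast and endothelial genes 5 rose, 5 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0995, adjusted p = 0.537 with an estimated correlation). Among 5 T and NK cell genes 2 rose and 1 fell, 2 and 1 adjusted over the list alone (camera adjusted p = 0.769, adjusted p = 0.906 with an estimated correlation). Among 11 neutrophil and monocyte genes 4 fell, 4 adjusted over the list alone (camera adjusted p = 0.11, adjusted p = 0.537 with an estimated correlation). Of 39 ribosomal protein genes 20 fell, 27 adjusted over the list alone (camera adjusted p = 2.18e-07, adjusted p = 0.697 with an estimated correlation), and of 13 mitochondrially encoded genes 2 rose, 1 adjusted over the list alone (camera adjusted p = 0.0293, adjusted p = 0.794 with an estimated correlation). Without donor 4 the counts were 1226 and 1014, the lowest of the 4, without the donor block 1215 and 893, and in a fit of only the 8 libraries compared 1299 and 862.

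In all 4 conditions, which again may share cultures, 1362 genes changed in WTAP KO, 876 higher and 486 lower, of 6603 called in any. Those with the largest smallest change that rose included ITIH5 and MS4A6E, which also rose in ZC3H13 KO, PTH2R, and the glutamate receptor subunit GRIN2A. ITIH5 rose by 9.93 ± 0.90 in unstimulated cells and by 9.02 ± 0.91, 8.57 ± 0.81 and 9.37 ± 0.87 under LPS, R848 and PolyIC (adjusted p = 8.85e-10, 2.53e-08, 5.08e-09 and 2.37e-09). Those that fell included the cytoskeletal and kinetochore genes STMN1, NDC80 and KNL1, the antimicrobial ribonuclease RNASE2 and the matrix protein LTBP2. KNL1 changed by −4.79 ± 0.49 in unstimulated cells and by −2.72 ± 0.48, −2.73 ± 0.47 and −3.15 ± 0.48 under the stimuli (adjusted p = 7.72e-09, 0.000158, 4.23e-05 and 7.58e-06). RNASE2 changed by −4.07 ± 0.84, −3.69 ± 0.81, −4.02 ± 0.83 and −4.52 ± 0.86 (adjusted p = 0.00024, 0.00167, 0.000396 and 0.000169). Without the donor 7 LPS library 1173 genes were higher and 873 lower, without the donor block 413 and 140, and in fits of only the libraries compared 99 and 52. Without donor 3 or 4 the counts were 406 and 210 or 236 and 92.

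**Figure D4:**
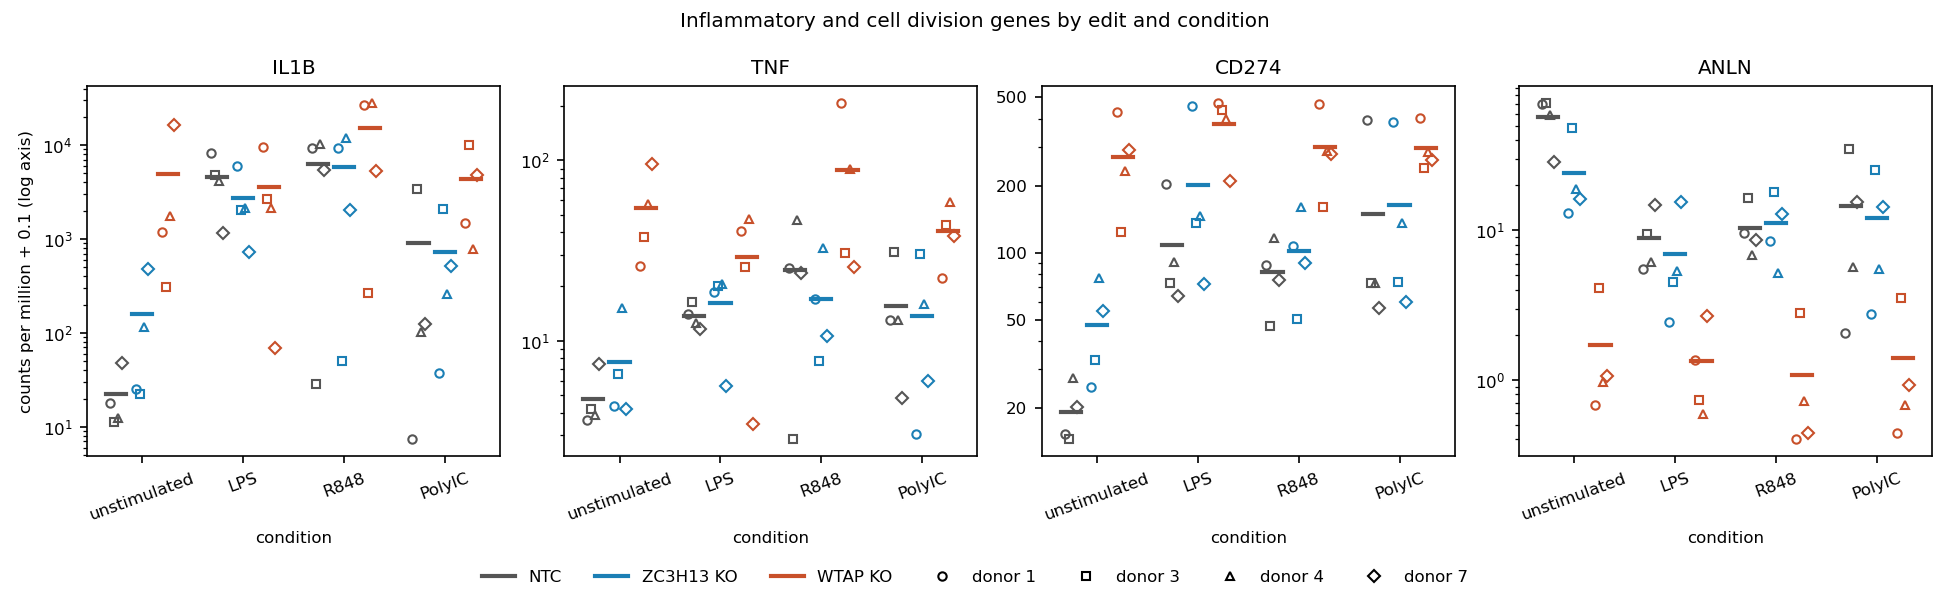
IL1B, TNF, CD274 and ANLN as CPM plus 0.1 on a log axis in the 3 edits and 4 conditions, 1 point per library and 1 symbol per donor, with a bar at the mean of each group. IL1B goes from a mean of 22.3 CPM in unstimulated NTC to 4920 CPM in unstimulated WTAP KO, where the 4 libraries lie between 305 and 16400 CPM.

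The response to LPS differed between WTAP KO and NTC in 132 genes, 47 with a higher and 85 with a lower response in WTAP KO. Those with the smallest adjusted p were the transcription factor MEF2C (2.55 ± 0.44, adjusted p = 0.00598), the RANK receptor gene TNFRSF11A (5.85 ± 1.02, adjusted p = 0.00598), CD180 (7.69 ± 1.34, adjusted p = 0.00598), CD1C (6.70 ± 1.22, adjusted p = 0.00745) and cyclin B1, CCNB1 (1.93 ± 0.36, adjusted p = 0.00811). Without the 7 libraries these differences were 2.30, 4.28, 3.43, 2.82 and 1.94 (adjusted p = 0.0057, 0.0142, 0.0496, 0.0848 and 0.0102). Of 24 NF-kB target genes 2 had a lower response, 19 adjusted over the list alone (camera adjusted p = 2.2e-16, adjusted p = 0.289 with an estimated correlation). Among 26 cytokines and chemokines 3 had, 16 adjusted over the list alone (camera adjusted p = 5.71e-08, adjusted p = 0.615 with an estimated correlation). The difference in response of IL1B was −8.17 ± 2.41 (adjusted p = 0.0837), and −7.24 without the 7 libraries (adjusted p = 0.0203). Of 26 cell cycle genes 3 had a higher response, 12 adjusted over the list alone (camera adjusted p = 1.9e-15, adjusted p = 0.31 with an estimated correlation). Of 9 dendritic cell genes 5 had a higher response, 5 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.176, adjusted p = 0.71 with an estimated correlation). No ribosomal protein gene and no mitochondrially encoded gene passed, none adjusted over the list alone (camera adjusted p = 0.000105 for a higher and 0.00839 for a lower list, adjusted p = 0.759 and 0.759 with an estimated correlation). The responses to R848 and PolyIC differed in no gene by edgeR (unadjusted p under 0.05 for 877 and 839 genes), in 67 and 37 genes with DESeq2, and in 95 and 7 without the 7 libraries. For LPS, no gene was called without donor 4, without the donor block or in a fit of only the 16 libraries compared, and 14 higher and 16 lower without the donor 7 library. Without donor 1 or 7 the counts were 12 and 11 or 16 and 22. They were 152 and 244 with DESeq2, 55 and 166 with limma-voom, 110 and 183 without the R848 and PolyIC libraries of donor 3, and 36 and 107 without the 7 libraries.

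The effects of the 2 edits were compared across genes. All 19, 10, 10 and 7 genes that rose in ZC3H13 KO in unstimulated, LPS, R848 and PolyIC cells also rose in WTAP KO, where independent lists would share 4.31, 1.06, 1.61 and 1.09. Of the 2 that fell in unstimulated cells 1 also fell in WTAP KO, against 0.38 for independent lists. Both lists were called against the same NTC libraries, so part of the excess may come from these. In 10 simulations with no effect of either edit at most 0.2 genes per list were called on average, too few to show what shared controls alone would give. With the donors split 2 against 2 in 6 ways so that the lists shared no library, a mean of 5.17, 0.5, 2 and 4.33 genes rose in ZC3H13 KO, and 4.67, 0.33, 2 and 3.67 of these rose in WTAP KO, against 0.423, 0.000811, 0.0824 and 0.219 for independent lists. Under PolyIC a mean of 21.5 genes fell in ZC3H13 KO in these splits, of which 0 fell in WTAP KO. Across 12618 genes, which are not independent replicates, the log2 fold changes of the 2 edits had r = 0.78, 0.75, 0.71 and 0.69 in the 4 conditions. In 20 simulations with no effect of either edit, r was 0.49, 0.50, 0.50 and 0.49. The share of genes with the same sign was 75.7, 75.9, 72.1 and 68.1%, against 66.4, 66.4, 66.6 and 66.3% in these simulations. The covariances, from mean log values, were 0.421, 0.267, 0.254 and 0.252 against 0.0674, 0.0785, 0.0788 and 0.0754 in the simulations, differences of 0.354, 0.189, 0.175 and 0.176. In the 6 donor splits that shared no library, the mean r was 0.58, 0.48, 0.37 and 0.37, and a mean of 66, 64.1, 58.4 and 58.1% of genes had the same sign. Over genes that changed over 2-fold in WTAP KO, the slope of the ZC3H13 KO on the WTAP KO change was 0.24, 0.27, 0.18 and 0.17 in the same splits.

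**Figure D5:**
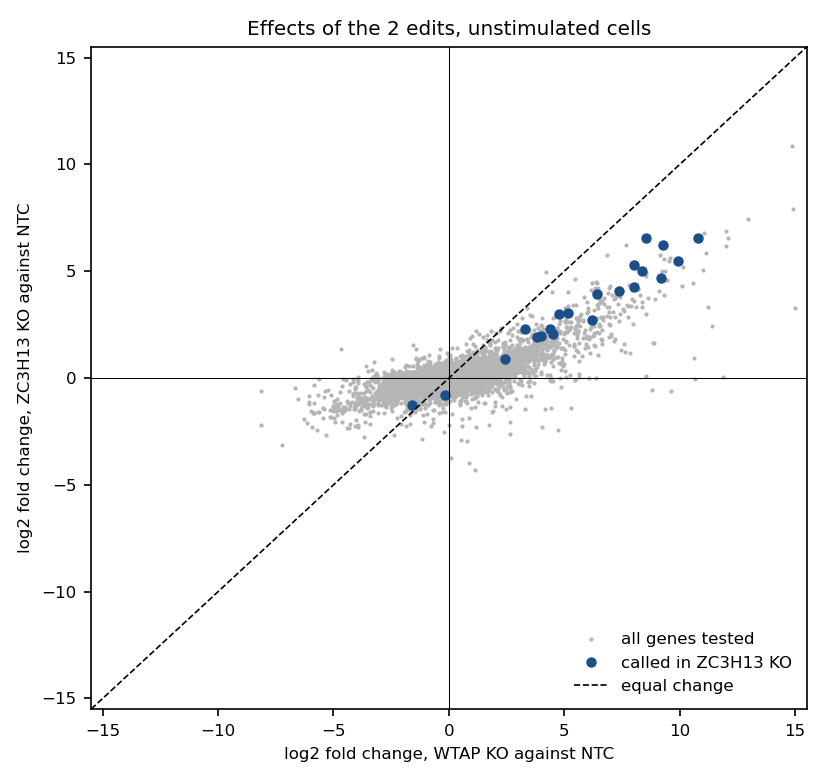
The log2 fold change against NTC in ZC3H13 KO plotted against that in WTAP KO, in unstimulated cells, 1 point for each of 12618 genes, with the 21 genes called in ZC3H13 KO in a darker colour. The dashed line marks equal change in both edits, and r across these genes, which are not independent replicates, is 0.78.

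ZC3H13 KO and WTAP KO were also compared with each other. In unstimulated cells 1490 genes were higher and 2055 lower in ZC3H13 KO than in WTAP KO. The leptin receptor LEPR was higher (2.86 ± 0.33) and the RNA kinase CLP1 lower (−1.22 ± 0.14), both with an adjusted p of 1.46e-06. TNF (−3.11 ± 0.74, adjusted p = 0.00226), IL6 (−4.31 ± 1.21, adjusted p = 0.00837), IL1B (−4.91 ± 1.76, adjusted p = 0.0345) and CD274 (−2.33 ± 0.45, adjusted p = 0.000313) were lower in ZC3H13 KO. So were 20 of 26 cytokines and chemokines, with 22 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.000326, adjusted p = 0.712 with an estimated correlation). Of 26 cell cycle genes 22 were higher in ZC3H13 KO, 26 adjusted over the list alone (camera adjusted p = 5.68e-15, adjusted p = 0.311 with an estimated correlation). Ribosomal protein genes were higher in ZC3H13 KO too, 25 of 39 in unstimulated cells, 0 under LPS, 16 under R848 and 15 under PolyIC, and 30, 0, 23 and 17 adjusted over the list alone (camera adjusted p = 1.6e-10, 4.35e-06, 5.94e-10 and 1.14e-06, adjusted p = 0.62, 0.712, 0.645 and 0.712 with an estimated correlation). Of 5 platelet and erythroid genes 0 were higher under LPS and 3 under R848, 5 and 4 adjusted over the list alone (camera adjusted p = 0.00575 and 0.0276, adjusted p = 0.382 and 0.537 with an estimated correlation), and 1 of 11 neutrophil and monocyte genes was higher under LPS, 1 adjusted over the list alone (camera adjusted p = 0.0367, adjusted p = 0.382 with an estimated correlation). Among 9 fibroblast and endothelial genes 4, 1, 1 and 3 were lower and 1, 0, 2 and 0 higher in the 4 conditions, 5, 3, 4 and 5 lower and 1, 2, 2 and 0 higher adjusted over the list alone (camera adjusted p = 0.383, 0.396, 0.733 and 0.17, adjusted p = 0.726, 0.74, 0.885 and 0.615 with an estimated correlation). Of 9 dendritic cell genes 3 were lower under LPS, and of 5 T and NK cell genes 3 in unstimulated cells and 3, with 1 higher, under PolyIC, or 5, 3 and 3 lower and 0, 1 and 1 higher adjusted over the list alone (camera adjusted p = 0.444, 0.661 and 0.57, adjusted p = 0.822, 0.884 and 0.861 with an estimated correlation). Under LPS 161 genes were higher and 311 lower, with the metalloproteinase ADAM28 at 2.21 ± 0.27 (adjusted p = 8.21e-06) and MS4A6E at −3.50 ± 0.48 (adjusted p = 8.9e-05). Under R848 964 were higher and 1288 lower, including TNF (−2.44 ± 0.71, adjusted p = 0.0162), CD274 (−1.5 ± 0.43, adjusted p = 0.0146) and SOCS6, a suppressor of cytokine signalling family member (−1.37 ± 0.17, adjusted p = 2.29e-06). Under PolyIC 1189 were higher and 1424 lower, including MS4A6E (−4.19 ± 0.50, adjusted p = 2.41e-06), IL10 (−1.98 ± 0.65, adjusted p = 0.0273) and the zinc finger gene ZNF234 (2.75 ± 0.31, adjusted p = 1.5e-06). Without the donor 7 library the LPS counts were 786 and 940, and fits of only the 8 libraries compared gave 0 under LPS, 545 and 783 under R848 and 438 and 761 under PolyIC. Fits without the donor block gave 593 and 945, 20 and 49, 296 and 496, and 395 and 546 in the 4 conditions. Leaving out donor 1 gave 903 and 1080 in unstimulated cells, 74 and 117 under LPS and 633 and 839 under PolyIC, and leaving out donor 3 gave 47 and 53 under LPS. Without donor 4 the 4 counts were 771 and 988, 9 and 22, 417 and 577, and 498 and 680. Without donor 7 they were 1001 and 1228, 419 and 484, 571 and 628, and 629 and 748.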

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

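The tests of the donor 3 and donor 7 libraries, the test with donors split between the edits, and the count of splits for the WTAP KO difference in LPS response were chosen after their results had been seen, while the other counts of splits, the mixing test and the thinning test were set before. The exchange test of the donor 7 library replaced a first version after that had been seen.

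In the R848 and PolyIC libraries of donor 3 the contrast between those stimuli ran against the labels. Across 2407 genes called between R848 and PolyIC in donors 1, 4 and 7, the R848 minus PolyIC difference of donor 3 had r = −0.77, −0.77 and −0.78 with that of the other donors in NTC, ZC3H13 KO and WTAP KO, where the left-out differences of donors 1, 4 and 7 had r from 0.17 to 0.92. A stimulus that did not act in donor 3 is argued against by the slope, −0.61 on average over the edits and not near 0. An exchange of the R848 and PolyIC labels of donor 3 stays open, since the highest of the 3 correlations was −0.77, in a test chosen from the same data. A donor that responds the other way stays open too, and the 2 cannot be told apart because the values would be the same, although the LPS response of donor 3 had r = 0.81 with that of the others (0.81, 0.79 and 0.58 for donors 1, 4 and 7).

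The LPS library of donor 7 in WTAP KO held 5 of the 9 measured genes of the dendritic cell list above each of the other 47 libraries: CD1A at 82.8 CPM against at most 6.21, CD1B at 299 against 8.48, CD1C at 185 against 13.7, CD1E at 210 against 8.41 and FCER1A at 24.9 against 6.51. CCR7, FLT3, IL3RA and LILRA4 were not above all others, and of 5 genes named after their values were seen ALOX15 (127 against 1.66), CCL17 (175 against 35.8), CLEC10A (97.7 against 11.8) and MMP12 (5910 against 331) were, but F13A1 (183 against 665) was not. An exchange with another of the 48 libraries is argued against by those 5 members, and over the 3000 most variable genes its highest r with any other library was 0.892, below the lowest such value of the other 47 (0.903). Cells without the WTAP edit are argued against only as the source of those 5 members, over 10 times above every other library of donor 7, and stay open for the rest: over 2515 genes that WTAP KO changed alike in the other 3 conditions the change here was 13.4% of that of the donor there, against 81.2 to 91.8% in donors 1, 3 and 4, and ITIH5, MS4A6E, RBM15 and WTAP were at 14.7, 9, 32 and 61.5 CPM, against 0.343, 0.274, 14.5 and 62 in NTC with LPS and at least 407, 44.3, 86.6 and 168 in the other WTAP KO libraries of the donor. Dendritic cells in this culture may be the source of the 5 members and stay open, with a median log2 difference of 3.51 over the list, as does a sample from outside the series, which was not tested.

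The ZC3H13 KO effect looked like a small version of the WTAP KO effect. Shared NTC libraries as the whole cause are argued against, since with donors split so that no library was shared the mean r over the 4 conditions was 0.45. WTAP KO material in the ZC3H13 KO libraries is argued against: the genes that rose would need a share of 11.3% of it, which would lower the genes that fell at least 4-fold in WTAP KO by no more than a log2 change of −0.17, while their median change was −0.53, below the bound in 6 of 6 donor splits. A difference in library size is argued against by thinning every library to 11861819 counts on tested genes, which removed up to 46.8% of a library, moved the unstimulated ZC3H13 KO change of 1928 of 12618 genes by over 0.1, and left the mean r at 0.44. A shared effect of losing m6A writer subunits therefore remains a hypothesis, which may hold only in part. These data hold no protein or m6A values, and the WTAP transcript was higher in both edits than in NTC.

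Every split of the libraries compared into 2 groups of 4 was refitted with edgeR, 32 of 35 of which could be fitted, in fits that left the other groups out. The real split was the 1 split with as many calls for LPS in NTC (2286 genes, at most 0 in any other split) and R848 in NTC (535, at most 88). It was so too for ZC3H13 KO unstimulated (290, at most 0) and under LPS (179, at most 24). For WTAP KO in the 4 conditions it was again the only such split (4866, 243, 2166 and 2161, at most 0, 11, 0 and 0). The same held for the edits against each other unstimulated, under R848 and under PolyIC (3693, 1328 and 1199, at most 0). Of these 32 splits only 8 part every donor pair as the real one does. The others put both libraries of a donor on 1 side, so they cannot exclude chance in this paired design. Among the 8, too few for a share under 0.05, the real split was again the 1 with as many calls for each of these results, with at most 0 genes in any other. The split with 88 genes put both donor 3 libraries on the unstimulated side. For ZC3H13 KO under R848 2 of 32 splits gave as many (2 genes, and 16 in the split that exchanged the labels of donor 3), so chance cannot be excluded. For PolyIC in NTC all 32 gave as many as the real 0, up to 401 genes in the split that kept donors 1 and 4 as labelled and put both donor 3 libraries on 1 side and both donor 7 libraries on the other. For ZC3H13 KO under PolyIC all 32 again gave as many as the real 0, up to 680 in the split that exchanged the edit labels of donors 3 and 7. Such numbers point to a structure of the samples other than the groups, and the fits of all 48 libraries with the donor block called 632 and 7 genes there. Among the 8 splits that part every donor pair, PolyIC in NTC gave at most 0 genes beside the real split and ZC3H13 KO under R848 and PolyIC 16 and 680. The edits against each other under LPS gave 0 in the real and in all 32 splits. The differences in response gave 0 in the real split, and all 32 splits gave as many, with at most 1, 0 and 180 genes elsewhere for LPS, R848 and PolyIC in ZC3H13 KO (180 in the exchange of donors 3 and 7) and at most 0 for R848 and PolyIC in WTAP KO. For LPS in WTAP KO the fit of 16 libraries also gave 0 in the real and every other split, and the fit of all 48 libraries gave 132 genes in the real split and at most 0 in the other 34, 1 of 35, and was 1 of 8 among those that part every donor pair.

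By Dixon's ratio of gap to range, 10 of 73 groups tested held a sample far from the others. Chance alone marks about 1 in 20. In unstimulated NTC it was CD163 at 5930 CPM in donor 1 against 1890 to 2560 (ratio 0.833), TNF at 7.32 in donor 7 against 3.55 to 4.09 (0.858) and ELOVL6 at 0.861 in donor 1 against 0.148 to 0.234 (0.88). In stimulated NTC it was CXCL10 with PolyIC at 5400 in donor 1 against 2.68 to 347 (0.936) and CXCL5 with R848 at 0.288 in donor 3 against 1010 to 1210 (0.838). In unstimulated WTAP KO it was IL1B at 16400 CPM in donor 7 against 305 to 1760 (0.91), and in donor 3 ANLN at 3.99 against 0.578 to 0.958 (0.889), ZC3H13 at 85.8 against 126 to 132 (0.857) and the total of 22300000 counts against 15900000 to 16700000 (0.879). In unstimulated ZC3H13 KO it was ITIH5 at 19.5 CPM in donor 7 against 0.525 to 3.57 (0.839). A test of the difference itself marked the LPS response of WTAP KO against that of NTC, with 132 genes, among them CD180 (7.69), CD1C (6.70), TNFRSF11A (5.85), MEF2C (2.55) and CCNB1 (1.93).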

How the results depend on the processing

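The omissions of the 7 libraries that stood apart, of the 6 of donor 3 and of the 1 of donor 7, the split of donors between the edits and the estimated correlation are read here beside settings fixed in advance, and the first 3 were chosen after the data were seen. Counts are of called genes, with the full fit in brackets. The cause of a change was not tested, apart from settings that leave libraries out or drop the donor block, which by construction have fewer libraries or a larger spread. Size factors of the relative log expression kind moved no count by over 1.5 times, nor the share of higher calls by over 10 points.
Leaving out 1 donor gave, from lowest to highest, 172 to 1917 for LPS in NTC (1573), 0 to 1251 for R848 (817) and 2 to 955 for PolyIC (632). For ZC3H13 KO in unstimulated, LPS, R848 and PolyIC cells it gave 0 to 22 (21), 0 to 2 (10), 0 to 13 (10) and 0 to 5 (7), and for WTAP KO 3566 to 4853 (5237), 448 to 2619 (2159), 2222 to 3188 (3727) and 2240 to 3180 (3681). For the WTAP KO difference in response it gave 0 to 112 for LPS (132), 0 to 2 for R848 (0) and 0 to 3 for PolyIC (0), and 0 to 0 for ZC3H13 KO (0). For the edits against each other it gave 1759 to 3130 (3545), 31 to 903 (472), 994 to 1739 (2252) and 1178 to 2620 (2613). Genes common to 4 conditions were 0 to 1 for ZC3H13 KO (5) and 328 to 1247 for WTAP KO (1362), called targets 1 to 3 (4), list calls 183 to 193 (204), and the r between edits 0.74 to 0.78, 0.69 to 0.75, 0.65 to 0.71 and 0.61 to 0.73 (0.78, 0.75, 0.71 and 0.69).
DESeq2 gave 1108 for PolyIC in NTC, 75, 20, 18 and 16 for ZC3H13 KO, 3, 3 and 2 for its differences in response, 396, 67 and 37 for those of WTAP KO, 775 for the edits under LPS, 12 common to ZC3H13 KO and 7 targets. With limma-voom PolyIC in NTC gave 983, ZC3H13 KO 2, 0, 0 and 0 with 0 common, and the WTAP KO differences for LPS and PolyIC 221 and 3. With no replicate block the stimuli in NTC gave 395, 201 and 7, ZC3H13 KO 3, 0, 0 and 0, WTAP KO 3464, 825, 2050 and 2108, its LPS difference 0, the edits 1538, 69, 792 and 941, and common genes 0 and 553. The block changed no other count by over 1.5 times. With only the libraries compared R848 and PolyIC in NTC gave 535 and 0, ZC3H13 KO 290, 179, 2 and 0, WTAP KO under stimuli 243, 2166 and 2161, its LPS difference 0, the edits under stimuli 0, 1328 and 1199, and common genes 0 and 151.
Without the 7 libraries the stimuli in NTC gave 2416, 2019 and 1476, ZC3H13 KO 48, 17 and 12 in unstimulated, LPS and PolyIC cells and 10 common, WTAP KO under LPS 3947, its R848 and PolyIC differences 95 and 7, and the edits under LPS 2027. Without the 6 of donor 3 R848 and PolyIC in NTC gave 1715 and 1206, ZC3H13 KO under R848 2 with 2 common, and the WTAP KO differences 293, 33 and 6. Without the 1 of donor 7 ZC3H13 KO gave 16 and 18 under LPS and R848 with 8 common, WTAP KO under LPS 3468 with 2046 common, its LPS and PolyIC differences 30 and 2, and the edits under LPS 1726. With donors split so that no library was shared the r between edits was 0.58, 0.48, 0.37 and 0.37. No list call held with an estimated correlation (0 of 204).
CD1C in WTAP KO under LPS (3.56) lay between −0.14 (without donor 7) and 4.26 when 1 donor was left out, and at −0.19 without the 7 libraries and −0.17 without the donor 7 library. Of 174 named values 146 were called, and 60 of these kept their call and direction under every setting fixed in advance that could be run. With 4 donors per group, 49 of 100 simulated 2-fold changes were recovered for ZC3H13 KO under LPS.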

Other observations

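Further changes in WTAP KO were read from the lists fixed beforehand, and the omission of the donor 7 library was chosen after the data were seen. Among the ribosomal protein genes that fell, RPL27 went from 300 ± 3.98 to 127 ± 34.7 CPM in unstimulated cells (−1.26 ± 0.22, edgeR adjusted p = 3.29e-05). RPS14 changed by −0.99 ± 0.19 (adjusted p = 8.87e-05). Of 23 cholesterol synthesis genes 10 fell in unstimulated WTAP KO, 1 higher and 12 lower adjusted over the list alone (camera adjusted p = 0.00534, adjusted p = 0.712 with an estimated correlation). Among them were SREBF2, a transcription factor of the pathway (−0.77 ± 0.18, adjusted p = 0.00104), and FDFT1, which encodes squalene synthase (−0.72 ± 0.17, adjusted p = 0.000809). Of 13 MHC class II pathway genes 4 rose in unstimulated cells, 3 under LPS, 6 under R848 and 2 under PolyIC, and 3, 7, 9 and 2 adjusted over the list alone (camera adjusted p = 0.0901, 0.000964, 0.0044 and 0.0637, adjusted p = 0.83, 0.685, 0.712 and 0.81 with an estimated correlation). Under LPS 3 of 9 dendritic cell genes rose too, and without the donor 7 library, in which such genes were high, 4 MHC class II pathway genes rose, 8 adjusted over the list alone (camera adjusted p = 0.00539), and 1 dendritic cell gene rose and 1 fell. HLA-DQA1, which encodes a chain of an antigen-presenting molecule, rose by 2.20 ± 0.48 in unstimulated cells (adjusted p = 0.000457) and by 2.64 ± 0.49 under R848 (adjusted p = 0.000112).

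Of 11 genes that read or remove m6A, 4 rose with WTAP KO in unstimulated cells, 5 under LPS, 4 under R848 and 5 under PolyIC, and 4, 5, 4 and 5 adjusted over the list alone, with 1 lower under PolyIC. The list did not pass in unstimulated cells and passed under the stimuli (camera adjusted p = 0.0601, 0.0411, 0.0185 and 0.0133, adjusted p = 0.537, 0.52, 0.392 and 0.375 with an estimated correlation). YTHDF3 rose by 1.05 ± 0.15 (adjusted p = 1.61e-06) and the nuclear reader YTHDC1 by 0.98 ± 0.15 (adjusted p = 5.56e-06) in unstimulated cells. Of 24 genes of the unfolded protein and integrated stress responses 7 rose and 5 fell in unstimulated WTAP KO, 7 and 5 adjusted over the list alone (camera adjusted p = 0.463, adjusted p = 0.794 with an estimated correlation). Under LPS, R848 and PolyIC 4, 10 and 6 rose and 0, 1 and 2 fell, and adjusted over the list alone 5, 11 and 6 rose and 0, 2 and 2 fell (camera adjusted p = 0.387, 0.0426 and 0.198, adjusted p = 0.759, 0.517 and 0.676 with an estimated correlation). The chaperone gene DNAJC3 rose by 2.09 ± 0.26 in unstimulated cells (adjusted p = 1.84e-07). DNAJB9 rose by 1.43 ± 0.25 (adjusted p = 3.17e-05) and by 1.58 ± 0.25 under R848 (adjusted p = 1.59e-05), and HSPA5, the main chaperone of the endoplasmic reticulum, by 1.25 ± 0.18 under R848 (adjusted p = 3.64e-06). Each named gene moved the same way in 4 of 4 donors. Of 24 p53 target genes 1 rose and 6 fell in unstimulated WTAP KO, 1 and 6 adjusted over the list alone (camera adjusted p = 0.769, adjusted p = 0.919 with an estimated correlation). Of 27 lysosome genes 6 rose and 5 fell, 6 and 5 adjusted over the list alone (camera adjusted p = 0.965, adjusted p = 0.989 with an estimated correlation).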
